A study of Eohaustorius estuarius with 16 samples.

How the data were processed

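Total RNA from whole bodies of control and cyfluthrin-exposed amphipods, 8 samples of each, was labelled with Cy3 and hybridised to a custom Agilent array with 1 colour. The labels do not say that each extract came from a separate animal or from separate exposures, so p-values measure the spread between these samples, which may in part be technical. The scanner files hold spot intensity values, and per the file headers these intensities were extracted with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. The processed intensity in the deposited files is background-subtracted and detrended within each array by that software, per the file headers, and is not normalized between arrays. The deposited series matrix holds log2 values, and the way the authors made them is not stated in the labels. Set against the scanner files, those log2 values were the quantile-normalized log2 processed intensity with the median of each probe subtracted (r rounding to 1 and slope rounding to 1 over all tested values), so scale, centring and direction are known. Each column matched the array of its own sample, and column medians lay between −0.043 and 0.041. No column of the matrix was left unused.

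Control spots were left out, as were spots flagged as outliers. From the remaining 15208 spots, log2 processed intensity minus the array's 75th percentile was averaged over the spots of a probe, giving 8507 probes. Each probe stands for 1 contig, and each contig was counted as a gene. Whether contigs that share an annotation come from 1 gene was not tested, so counts of contigs may exceed counts of genes. A probe counted as detected on an array where at least 0.5 of its spots were flagged well above background. Probes detected on at least 6 of the 8 arrays of either group were tested, which left 5556, of which 2295 had an informative annotation. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, group as the only term) and Benjamini-Hochberg adjustment at 0.05. The main test, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

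Gene lists were 24 sets of annotation words, matched to the annotation column of the scanner files. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The annotation words of the ribosomal list were meant for cytosolic proteins but also matched mitochondrial ones. The named genes are the 12 with the highest and the 12 with the lowest log2 change among annotated probes past the threshold with the same direction in every fit that left out 1 array, together with the 2 members with the smallest p in each list described and up to 2 unannotated probes per direction. Members of lists, other contigs of the same families and the 28 probes with large rises that fall outside this rule were named after their values were seen. Shares of probes detected and distances between arrays were compared with two-sided exact permutation tests. The distance of an array is the median over tested probes of its absolute log2 difference from the median of the other arrays in its group.

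Slides and positions were taken from the file headers. The 4 slides held 4 arrays each, 2 of either group, and each slide was one scan. Alternatives changed the normalization, the background correction, the filter on dim probes, the moderation, the threshold and the weights of arrays, added slide, row or replicate number to the fit, left out each array in turn, or used the series matrix. Because each contig was counted as a gene, the alternative of using the other probes of a gene was not run.

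The test was checked on simulated data with the means and spreads of the 5556 tested probes for the comparison of cyfluthrin with control. Of 200 changed probes, limma recovered 23.9% of those changed 1.5-fold, 61.2% of those changed 2-fold and 87.9% of those changed 4-fold, with 9 false calls among 124. A list of 51 members lowered 1.5-fold was recovered by camera, with 0 of 20 other lists called. Each probe was simulated independently of the others. The check therefore does not show how the list test behaves when genes vary together. No reference genome was used here, so contigs carry no coordinates.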

Results

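Whole-body RNA of the estuarine amphipod Eohaustorius estuarius, a burrowing crustacean used in sediment toxicity tests, was measured on 16 one-colour microarrays. Control animals had lived for 10 days in solvent-spiked sediment (8 arrays), and exposed animals in sediment spiked with the pyrethroid insecticide cyfluthrin at a nominal 1.6 µg/kg (8 arrays). Pyrethroids act on voltage-gated sodium channels of nerve cells. All extracts came from a single laboratory, and these arrays were labelled, hybridised and scanned in 1 of the 6 laboratories of a comparability study. The arrays of the other laboratories were not analysed here. The question addressed was which transcripts differed between exposed and control animals. The array carried 8507 probes, each designed on its own assembled contig. Of these, 3229 had an informative annotation, and genes are named below by that annotation with the contig number. The files mark the contigs as unmapped, so no genome coordinates or exon annotation are given.

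The signal over background differed between arrays. The share of probes well above background was 70.2% ± 8.9 in controls and 57.3% ± 10.8 after cyfluthrin (SD, n = 8 each), ranging from 38.8% in cyfluthrin replicate 4 to 80.8% in control replicate 2. The difference of −12.9 percentage points gave p = 0.0205 (two-sided exact permutation test over 12870 regroupings), and p = 0.0615 after Benjamini-Hochberg adjustment over 6 array measures. Within the 4 slides, each with 2 arrays of either group, the difference was −13.5, −9.42, −19.9 and −8.88 points. No spot was saturated. The number of arrays limits the precision of the values below.

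**Figure D1:**
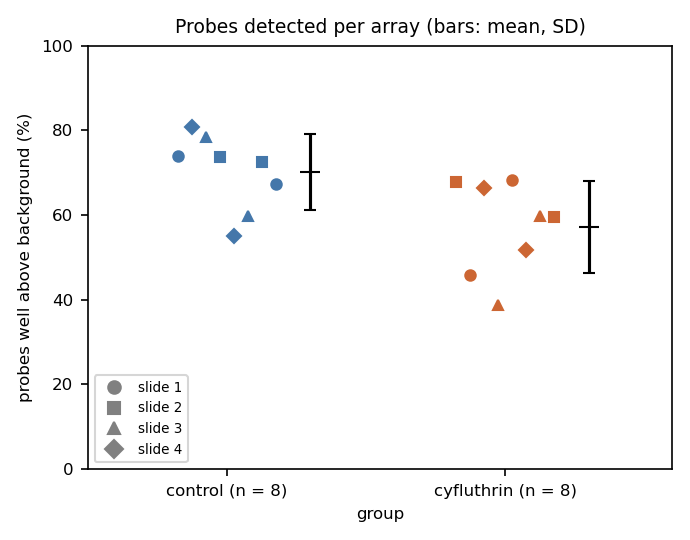
Share of probes well above background on each array (vertical axis, percent) for the 8 control and 8 cyfluthrin arrays, with the slide given by the symbol and the mean and SD beside each group. The lowest array, cyfluthrin replicate 4, stands at 38.8% and the highest, control replicate 2, at 80.8%.

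After cyfluthrin, 3 of 5 contigs annotated as heat shock protein 70, 3 of 4 hemocyanin contigs and 13 of 51 digestive enzyme probes were lower, and a set of 28 probes was far higher, by a median of 3.49 on the log2 scale. Of 5556 probes tested, 112 were higher and 188 lower (limma, adjusted p under 0.05), and 41 of the higher and 67 of the lower ones differed by at least 2-fold. Annotated genes made up 44 of the higher and 87 of the lower probes. When the background was corrected with normexp, 81 of these 131 calls did not pass with the 75th percentile and 27 with quantile normalization. All tested probes had a median log2 change of −0.14, so the medians of gene lists are given relative to that shift. The balance of directions depended on the scaling, the arrays used and the filter. In the main test, 37.3% of calls were higher. The share was 52.8% with quantile normalization (196 higher and 175 lower) and 50.3% in the authors' deposited values (151 higher and 149 lower). With the 75th-percentile scaling kept, it ran from 31% without cyfluthrin replicate 6 to 52.3% without the 2 arrays of lowest detection. Over probes well above background on all arrays it was 46.7%, and their median log2 change was −0.016. With slide as a block, 102 were higher and 155 lower.

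Probes annotated as chaperones moved in both directions. Of 51 tested probes in the list of heat shock proteins and chaperones, 4 rose, 5 fell and 42 did not pass the test, and adjusted over the list alone 5 rose and 5 fell. The largest falls of any named gene were in 3 contigs of heat shock protein 70, the chaperone that binds unfolded polypeptides. Contig 2561 went from 3.05 ± 0.51 in controls to 0.39 ± 0.35 after cyfluthrin on the normalized log2 scale (SD, n = 8 each), which is 6.31-fold lower (log2 change −2.66 ± 0.21 SE, adjusted p = 3.05e-07 by limma). Contigs 2087 and 2088 were 5.97-fold and 5.34-fold lower, with 7 and 5 of 8 cyfluthrin arrays well above background. With normexp and the 75th percentile their log2 changes were −1.60 and −0.955 and still passed. A contig of heat shock protein 90, contig 6339, was 4.71-fold lower on the fitted scale, but it was well above background on 7 control arrays and 1 cyfluthrin array, and its log2 change was −0.35 and did not pass with normexp and the 75th percentile. A small heat shock protein (contig 327) fell by 1.47 on the log2 scale (adjusted p = 0.000644), with a log2 change of −0.855 with normexp and the 75th percentile. Other contigs annotated as heat shock protein 70 did not pass, with log2 changes of −0.06 for contig 2086 and −0.31 for contig 2089. The 4 members of the list that rose were heat shock protein 90 in contigs 4879 and 5659 (14.3-fold and 11.2-fold), the heat shock protein 90 partner p23 (contig 5795, 11.2-fold) and heat shock protein 83-1 (contig 4735, 10.8-fold). A relative of heat shock protein 70 outside the list, annotated as stress-seventy subfamily A protein (contig 4071), was 9.99-fold higher (adjusted p = 2.5e-05 by limma). These 4 members and contig 4071 all belong to the 28 probes with large rises described below, whose origin stays open. Outside the list and that set, contig 1566, annotated as lethal essential for life L2EFL, rose by 0.685 on the log2 scale (adjusted p = 0.0179 by limma). With normexp and the 75th percentile contig 1566 did not pass (0.505). Other contigs of heat shock protein 90 did not pass, with log2 changes of −0.35 (contig 1253), −0.82 (contig 1375) and −0.945 (contig 7391). The list as a whole did not pass (camera adjusted p = 0.614).

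Of the 300 called probes, 95 had ranges that did not overlap between exposed and control arrays. Among these were the 12 named genes with the largest rises, which were picked for the size of their change. Besides the chaperones they were a translation elongation factor-like protein (contig 4158, 12.6-fold), actin (contig 4390, 12.5-fold), a cysteine protease (contig 7908, 12.1-fold), an SH2 domain protein (contig 4609), a protein annotated as the DNA repair factor RAD50 (contig 3691, 12.9-fold) and one annotated as myeloid leukemia (contig 7113, 10.8-fold). They also included the glycolytic enzyme fructose bisphosphate aldolase (contig 6580, 10.8-fold) and a 60S ribosomal protein (contig 6676). The SH2 domain protein was well above background on 1 of 8 control arrays and the aldolase on 5 of 8, and the fitted log2 change of the SH2 domain protein ran from 1.28 to 3.96 over the alternative settings, past the threshold in each. With normexp and quantile normalization the rises kept their calls but were smaller, with log2 changes of 0.93 for the 60S ribosomal protein, 1.44 for aldolase, 1.92 for heat shock protein 83-1, 1.92 for heat shock protein 90 in contig 5659 and 3.33 for contig 4879. The translation elongation factor-like contig went from 0.48 ± 0.60 to 4.13 ± 0.59 (SD, n = 8 each; log2 change 3.65 ± 0.28 SE, adjusted p = 2.66e-07 by limma). The 60S ribosomal protein was not well above background on any control array, so its rise is given as at least 10.6-fold (adjusted p = 2.49e-06 by limma), a bound that holds only for the background correction of the main test. For such a bound, the dim group was set at the higher of its own signal and the lowest signal of any probe well above background on that array. On the log2 scale 28 probes rose by over 2.5, a limit chosen after the values were seen, and the next called probe rose by 2.09. Of the 28, 16 were named and 11 had no annotation. The remaining probe was annotated as a hypothetical protein of Vitis vinifera (contig 6094, log2 change 3.17). The median change of the 28 was 2.40 with normexp and the 75th percentile and 2.38 with normexp and quantile normalization. Among the named ones was a probe annotated as ALVEOLIN3 of the dinoflagellate Karlodinium veneficum (contig 4088, log2 change 2.83), alveolins being membrane-skeleton proteins of alveolates. It was well above background on 4 control and 6 cyfluthrin arrays. Its log2 change was 1.18 with normexp and the 75th percentile and 0.87 with normexp and quantile normalization. The median over the 28 probes lay between −3.22 and −0.31 on the control arrays and between 0.60 and 2.23 on the cyfluthrin arrays, and its change within slides was 2.60 to 3.96. In a list of annotations from other organisms fixed beforehand, none of 3 tested probes passed (limma, with 0 at an unadjusted p under 0.05). That list did not match contigs 4088 and 6094. Outside the list and the 28 probes, an orf16-lacZ fusion protein (contig 4431) and a cell wall-associated hydrolase (contig 4391) rose by 2.09 and 1.70. Both calls held in every alternative setting.

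**Figure D2:**
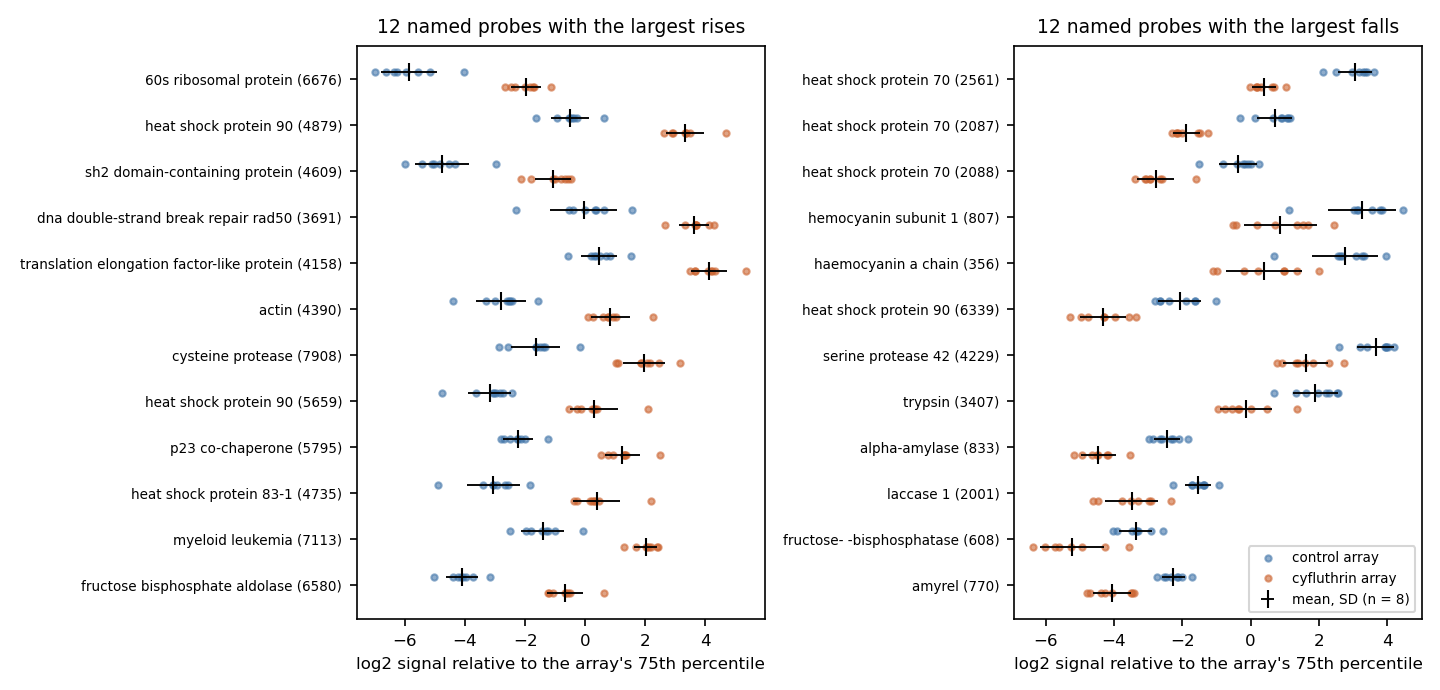
Normalized log2 signal (horizontal axis, relative to each array's 75th percentile) of the 12 named probes with the largest rises and the 12 with the largest falls, one point per array, with mean and SD of 8 arrays per group and contig numbers in parentheses. Heat shock protein 90 in contig 4879 rose 14.3-fold while heat shock protein 70 in contig 2561 was 6.31-fold lower.

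**Figure D3:**
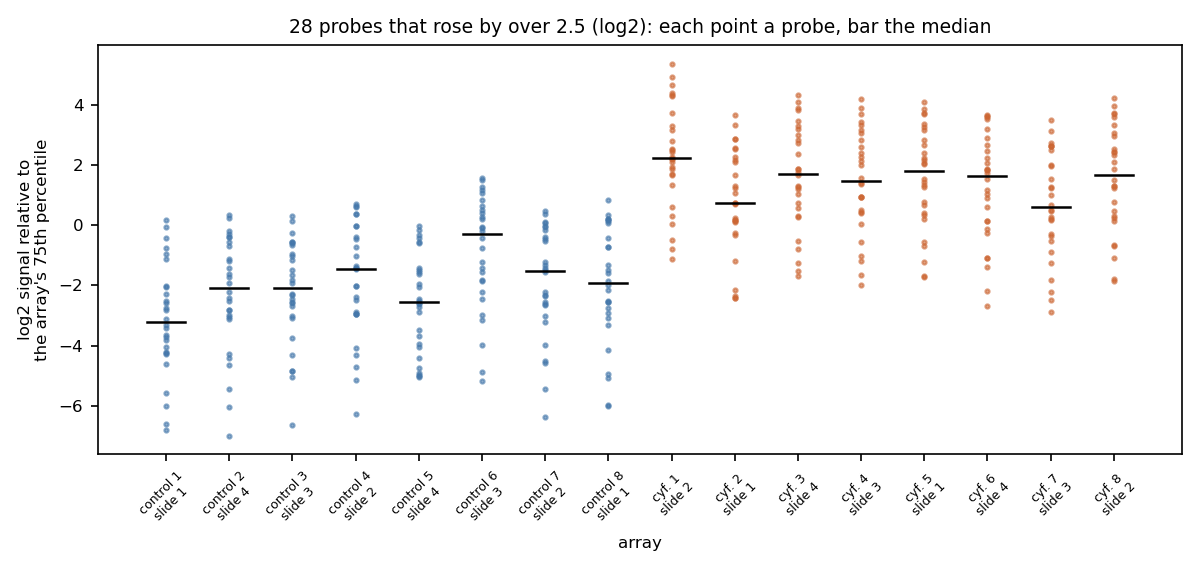
Normalized log2 signal (vertical axis) of the 28 probes that rose by over 2.5 on the log2 scale, on each of the 16 arrays, with the median of the 28 as a bar. The medians run from −3.22 to −0.31 in controls and from 0.60 to 2.23 after cyfluthrin.

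A part of the digestive enzymes was lower in exposed animals. Of 51 tested probes, 13 fell, 1 rose and 37 did not pass, and adjusted over the list alone 23 fell and 3 rose. The count of falls was 7 with normexp and the 75th percentile, 25 with array weights and 22 without cyfluthrin replicate 1. It was 20 without the 2 arrays of lowest signal in the single spike-in feature a107 (cyfluthrin replicate 1 and control replicate 5). The starch-digesting alpha-amylase in contig 833 was 4.01-fold lower on the fitted scale (SE 0.24 on the log2 scale, adjusted p = 2.73e-05 by limma), but it was well above background on 1 of 8 cyfluthrin arrays, and with normexp and the 75th percentile its log2 change was −0.09 and did not pass. The brighter alpha-amylase contig 2702 fell by 1.29 (adjusted p = 0.0105 by limma). It was well above background on every array and still passed with normexp and the 75th percentile (−1.20). A further alpha-amylase, contig 7733, fell by 0.71, a call lost in 22 of 31 alternative settings. The protease trypsin in contig 3407 was 4.11-fold lower (−2.04 ± 0.33 SE, adjusted p = 9e-04). Cathepsin D, an aspartic protease, fell in contigs 2587 and 2525, with log2 changes of −1.47 and −1.45 and SEs of 0.17 in both, but with normexp and the 75th percentile contig 2587 did not pass (−0.49). Lipase (contig 1588), carboxypeptidase A2 (contig 301) and a cationic trypsin (contig 769) also fell, the call of carboxypeptidase A2 being lost in 8 of 31 alternative settings and that of the cationic trypsin in 11 of 31. A chymotrypsin-type peptidase (contig 382) rose by 0.61 ± 0.13 SE on the log2 scale (adjusted p = 0.00776), and its call was lost with normexp and the 75th percentile (0.38) and with the replicate number as a block. Outside the list, amyrel (contig 770), an amylase relative, was 3.51-fold lower with 3 of 8 cyfluthrin arrays well above background, and did not pass with normexp and the 75th percentile (log2 change −0.18). Serine protease 42 (contig 4229) was 4.13-fold lower. The median of the list lay 0.50 below that of all tested probes (relative log2 median −0.50), with camera adjusted p = 8.38e-05 at a preset correlation of 0.01. With an estimated correlation of 0.067 the adjusted p was 0.353 and the unadjusted p 0.0168. The relative median was between −0.65 and −0.16 within the 4 slides, and the adjusted p was 0.000221 with slide as a block. It was −0.157 with normexp and the 75th percentile (adjusted p = 0.0113) and −0.19 with normexp and quantile normalization (adjusted p = 1.79e-05).

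Most hemocyanin contigs were lower. Hemocyanin is the copper protein that carries oxygen in crustacean hemolymph. Of 4 tested contigs, 3 fell, and the list test needed 5. Without the filter on dim probes 6 contigs were tested as a list and passed (camera adjusted p = 0.00122, or adjusted p = 0.298 with an estimated correlation). Hemocyanin subunit 1 in contig 807 went from 3.25 ± 0.99 to 0.87 ± 1.07 (SD, n = 8 each), a 5.21-fold lower level (log2 change −2.38 ± 0.47 SE, adjusted p = 0.00592 by limma). Its probe was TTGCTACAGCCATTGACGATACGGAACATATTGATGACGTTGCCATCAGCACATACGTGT. A contig annotated as the hemocyanin of the spiny lobster (contig 356) was 5.16-fold lower (adjusted p = 0.00686 by limma) and was read with the probe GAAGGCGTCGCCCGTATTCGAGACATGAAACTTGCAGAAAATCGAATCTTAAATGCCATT. A further contig with that annotation, contig 1458, fell by 1.46 on the log2 scale, but did not pass with normexp and the 75th percentile (−0.48). Another contig of hemocyanin subunit 1, contig 3682, had a log2 change of −0.23 ± 0.34 SE and did not pass. Contigs 807 and 356 moved together over the arrays, both being lowest among controls in control replicate 7. Whether they read 1 transcript was not tested. Laccase 1 (contig 2001), a copper-containing phenol oxidase, was 3.86-fold lower with 4 of 8 cyfluthrin arrays well above background, and did not pass with normexp and the 75th percentile (log2 change −0.37).

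A few cuticle and chitin genes were lower. Of 60 tested probes, 5 fell, none rose and 55 did not pass (8 fell adjusted over the list alone), while 56 of the 60 had a negative log2 change. None of the 5 passed with normexp and the 75th percentile, and the calls of the cuticle proteins in contigs 4608, 1231 and 1172 were lost in 18, 17 and 17 of 30 alternative settings. Midgut chitinase (contig 3952) fell by 0.89 ± 0.19 SE on the log2 scale (adjusted p = 0.00795 by limma), but did not pass with normexp and the 75th percentile (−0.37). Chitinase 1 (contig 751) fell by 1.13, but its log2 change was 0.14 when the background was corrected with normexp and the 75th percentile was kept. The relative median of the list was −0.53 (camera adjusted p = 0.0107), and the adjusted p was 0.658 with an estimated correlation. Within slides the relative median ran from −1.31 to 0.01, and with slide as a block the adjusted p was 0.00841. The adjusted p was 0.052 without control replicate 7 and 0.112 with normexp and the 75th percentile. Over the 18 members that were well above background on all 16 arrays, the relative median was −0.16 and the adjusted p 0.288.

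Of 9 tested probes in the list of arginine kinase and glycolysis, 2 rose and 2 fell, and 5 did not pass (4 rose and 3 fell adjusted over the list alone). The list did not pass (camera adjusted p = 0.344, or adjusted p = 0.658 with an estimated correlation). The risers, fructose bisphosphate aldolase and glyceraldehyde 3-phosphate dehydrogenase (contig 2699, annotated as glyceraldehyde 3-phosphate; 9.74-fold higher), both belonged to the 28 probes described above. Hexokinase, the first enzyme of glycolysis, fell in contigs 7050 and 5320, with log2 changes of −1.21 ± 0.23 and −1.03 ± 0.17 (SE), but contig 7050 did not pass with normexp and the 75th percentile (−0.535). The gluconeogenic enzyme fructose-bisphosphatase (contig 608) was not well above background on any cyfluthrin array and was at least 2.5-fold lower, although its log2 change was 0.07 with normexp and the 75th percentile. Of 48 mitochondrial respiratory chain probes, none rose and 2 fell. They were NADH dehydrogenase (contig 3717), with a log2 change of −0.83, and a subunit of the vacuolar ATP synthase (contig 1270), with −1.22. The former did not pass with normexp and either scaling (−0.09 with the 75th percentile and −0.27 with quantile normalization). The latter belongs to a proton pump of vacuoles and is not part of the respiratory chain. Its call was lost in 18 of 30 alternative settings, in 1 of which its sign also changed.

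Immune and structural lists held a few lower transcripts without passing the list test. Of 47 immunity probes, 4 fell and none rose, with camera adjusted p = 0.578. They were 2 contigs of an i-type lysozyme-like protein, an enzyme that breaks bacterial walls, a C-type lectin (contig 3522) and a toll-like receptor (contig 5830). The lysozyme-like contig 2944 fell by 1.10 and the lectin fell by 1.14 on the log2 scale, but with normexp and the 75th percentile their changes were 0.01 and 0.17. The other lysozyme-like contig, contig 734, had a change of 0.08 there and lost its call in 21 of 30 alternative settings. Of 18 extracellular matrix probes, secreted mucin (contig 3934) and collagen alpha-2 (contig 1569) fell (camera adjusted p = 0.197). The call of mucin was lost in 13 of 30 alternative settings and that of collagen alpha-2 in 19 of 31. Of 32 muscle probes only muscle LIM protein (contig 285) passed, with a log2 change of −0.72, which became 0.25 with normexp and the 75th percentile. Of 21 antioxidant probes only catalase (contig 322), which breaks down hydrogen peroxide, passed, and it fell by 0.63. Its call was lost in 15 of 31 alternative settings. Outside the list, contig 7422, annotated as alkyl hydroperoxide reductase and thiol-specific antioxidant, was 8.18-fold higher (adjusted p = 2.66e-07 by limma). It belongs to the 28 probes with large rises, and its log2 change was 1.88 with normexp and the 75th percentile. Of 9 moult hormone probes only a broad-complex core protein (contig 1795), a transcription factor of the moulting cascade, passed, and it fell by 0.82, but it did not pass with normexp and either scaling (−0.12 with the 75th percentile and −0.29 with quantile normalization).

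Detoxification genes metabolise many insecticides, and those matched by the 2 lists did not pass one by one. None of 32 phase I probes and none of 15 phase II and transport probes reached the threshold (limma), with 12 and 3 at an unadjusted p under 0.05. The phase I probe with the smallest p was a cytochrome P450 monooxygenase (contig 8118) with a log2 change of 0.74 ± 0.21 SE (adjusted p = 0.0518), and a carboxylesterase (contig 2534) had −0.59 ± 0.19 SE (adjusted p = 0.0732). Under alternative settings the P450 monooxygenase passed as higher in 12 of 31 and the carboxylesterase as lower in 3 of 31, and a glutathione S-transferase (contig 6382) as lower in 2 of 30. The phase I list had a relative median of −0.14, with camera adjusted p = 0.276. Its members moved on balance downwards by fry (adjusted p = 0.00443), a test that does not compare them with other genes. A probe that the list did not match, contig 1281, is annotated as a cytochrome family protein of subfamily j. It fell by 0.83 ± 0.16 SE on the log2 scale (adjusted p = 0.00424 by limma). Its call was lost in 1 of 31 alternative settings, normexp with the 75th percentile (−0.38). The neural and ion channel list had 7 tested probes, and none passed (limma; 0 at an unadjusted p under 0.05). Its probes with the smallest p were the synaptic glycoprotein SC2 (contig 2745, −1.03 ± 0.50 SE) and a muscarinic acetylcholine receptor (contig 2964, −0.81 ± 0.48 SE), both of which changed sign with normexp and the 75th percentile (0.13 and 0.21).

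A list of ribosomal proteins, 7 of whose 12 tested members are mitochondrial, had a relative median of 0.25 (camera adjusted p = 0.0231, or 0.658 with an estimated correlation), and 1 member, ribosomal protein L22 (contig 481), rose by 0.54 ± 0.14 SE, a call lost in 10 of 31 alternative settings. That list call was lost without control replicate 3 (adjusted p = 0.0717), control replicate 6 (0.0566), cyfluthrin replicate 1 (0.079) or cyfluthrin replicate 8 (0.0582). It was also lost with normexp and the 75th percentile (relative median 0.01, adjusted p = 0.687), without the filter on dim probes (0.112), over probes well above background on all arrays (0.288) and by fry (0.17). Of 71 translation factor probes the elongation factor-like contig alone passed (camera adjusted p = 0.0933). Of 56 proteasome and ubiquitin probes, 2 rose, among them a ubiquitin-conjugating enzyme (contig 3343) by 0.49 on the log2 scale, which did not pass with normexp and the 75th percentile (0.24), and the call of the other (contig 6443) was lost in 16 of 30 alternative settings. The lipid list held 1 riser among 15 probes, the very low-density lipoprotein receptor (contig 3297), 2.98-fold higher (adjusted p = 8.08e-05 by limma), with a log2 change of 0.98 with normexp and the 75th percentile and 0.79 with normexp and quantile normalization. No probe passed among 14 of vitellogenin and reproduction, 12 of the cell cycle and histones, 8 of sodium, potassium and osmotic transport, 8 of apoptosis or 4 of the visual system (limma; 5, 2, 0, 0 and 0 at an unadjusted p under 0.05). In all, 3 of 21 lists with at least 5 tested members passed by camera, none with an estimated correlation, and 11 of 100 splits of the arrays gave at least 3 lists.

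**Figure D4:**
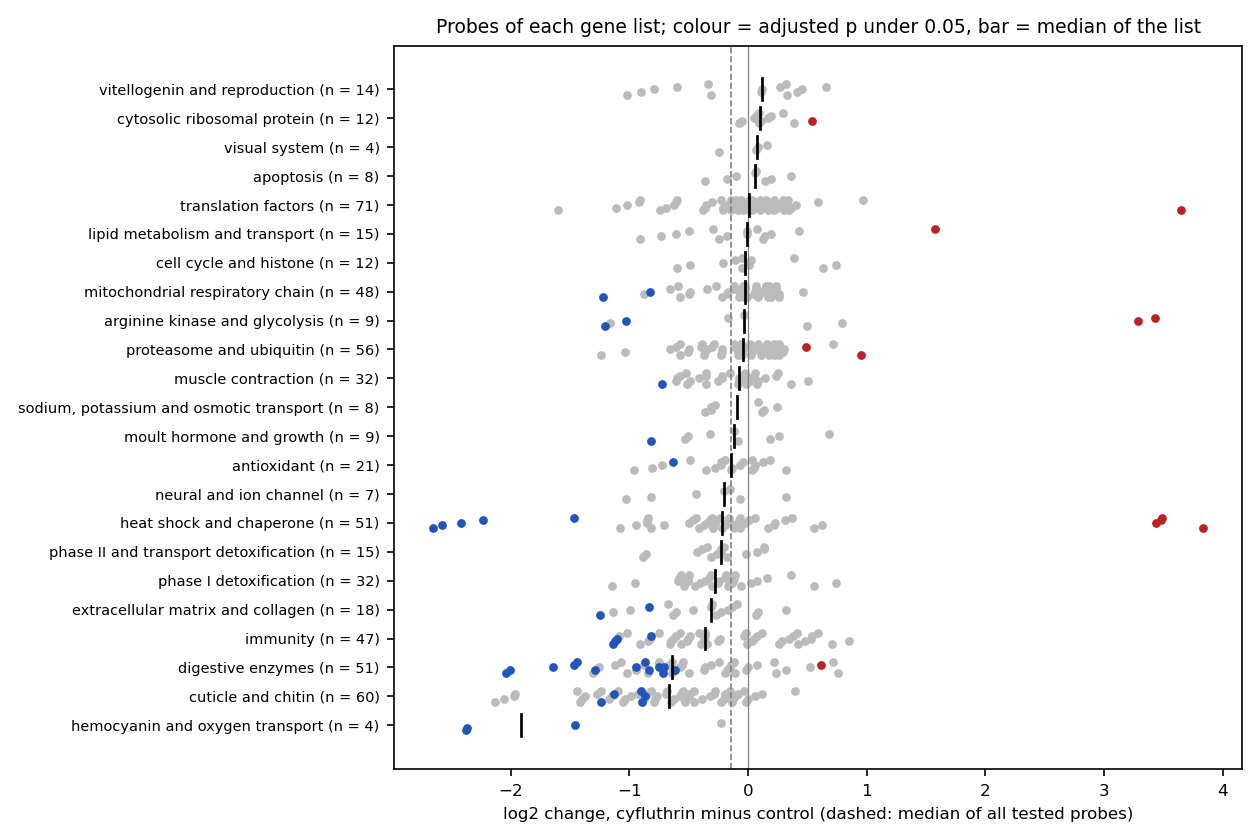
Log2 change of every tested probe of each gene list (horizontal axis, cyfluthrin minus control), with probes past the adjusted threshold in colour, the median of each list as a bar and the median of all tested probes as a dashed line at −0.14. The 3 called hemocyanin probes and 13 called digestive enzyme probes lie on the lower side.

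Among the probes without annotation, contig 7311 rose 8.50-fold (adjusted p = 5.73e-09 by limma) and contig 7650 rose 13.6-fold. Both belong to the 28 probes with large rises. With normexp and quantile normalization their log2 changes were 2.71 and 2.30. Contig 2434 fell by 1.17 ± 0.13 SE and contig 3490 by 0.83 ± 0.10 SE on the log2 scale.

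The scatter between arrays was compared last. The median distance of an array from the other arrays of its group was 0.294 ± 0.065 in controls and 0.314 ± 0.147 after cyfluthrin on the log2 scale (SD, n = 8 each). The difference of 0.0195 gave p = 0.803 (two-sided exact permutation test). Without cyfluthrin replicate 1, which had the largest distance at 0.651, the difference was −0.0293. Within slides it was −0.0383, 0.151, −0.00473 and −0.0305.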

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

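The tests of slides, of gene families, of correlated residuals and of heterogeneity in this part were chosen after the results were seen, while those of dim probes and of other splits were set out before. The covariate of negative-control signal was not among the settings fixed beforehand.

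The 28 probes with the largest rises were the pattern furthest from the rest of the array. Their deviations from the group means ran in parallel over the 16 arrays. The median pairwise correlation was 0.699, against at most 0.159 in 1000 random sets of the same mean signal. Such a pattern could arise if RNA of another organism were more abundant in the exposed extracts. The annotations do not settle which organism, as contig 4088 names an alveolate and contig 6094 Vitis vinifera. The tables argue against a background difference (median change 3.48 with the negative-control signal as a covariate, smallest 2.97; 2.38 with normexp and quantile normalization), against slides (lowest within-slide median 2.60) and against induction of whole amphipod gene families, since the other 25 tested contigs of those families had a median change of −0.13 with 0 called higher. Parallel deviations would also arise if single amphipod genes were regulated together, so a response of particular family members to cyfluthrin stays open. The 3 tested probes of the list of other organisms did not pass, and the contigs were not matched to any genome.

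The lower digestive enzymes were weighed against 3 explanations. The 29 members well above background on all 16 arrays had a relative median of −0.559 (SE 0.149), which argues against a loss of dim probes. The relative median was −0.41 (SE 0.11) with the negative-control signal as a covariate, which argues against a background difference that follows that signal, but it was −0.157 with normexp and the 75th percentile and −0.19 with normexp and quantile normalization, so how far its size rests on the background correction stays open. An even fall of all members, as a smaller share of digestive-gland RNA alone would give, is opposed by their heterogeneity (p = 1.96e-51, chi-square) and by the 1 member that rose, whose call was lost with the replicate block and with normexp and the 75th percentile. A smaller share of gland RNA combined with changes within the gland, or with members that other tissues express, and a response of the gland to cyfluthrin stay open.

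The difference in the share of detected probes was below 0 within all 4 slides, the nearest to 0 being −8.88 points. Slides, which held 2 arrays of either group each, do not account for it. The column on the slide was not balanced, with only cyfluthrin replicates 2, 3 and 6 in column 3. Column was not put into any fit, so a difference between columns stays open. With the negative-control signal as a covariate the difference was −8.9 points (SE 4.85), and a background difference and an effect of exposure cannot be told apart, because that error spans both the full −12.9 points and a far smaller difference.

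In 100 splits of the 16 arrays, the real one included, 2 gave a single-direction count of at least 112 and 2 one of at least 188. The real split gave 112 higher and 188 lower, and the highest other split gave 287. Chance is thus unlikely for both counts but cannot be excluded, because that other split exceeded them. That other split put 6 of the 8 cyfluthrin arrays on one side, together with control replicates 5 and 7. For the count of lists, 11 of the 100 splits gave at least the real 3, up to 6, so chance cannot be excluded.

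Arrays lying apart from their group were looked for in 78 groups of 8 values, and 15 were found. Chance gives about 3.9, but several groups are probes that moved together. The 15 are therefore not separate findings, and their number cannot be weighed directly against 3.9. Cyfluthrin replicate 2 had the highest 75th percentile signal of its group (334 against 255 to 286) and cyfluthrin replicate 4 the highest spot variation (8.98% against 3.64% to 6.03%). Distance from the group was 0.434 in control replicate 5 (others 0.237 to 0.324) and 0.65 in cyfluthrin replicate 1 (others 0.185 to 0.361). Cyfluthrin replicate 1 also stood highest for heat shock protein 90 (contig 4879, 4.68, and contig 5659, 2.1), the elongation factor-like protein (5.36), actin (2.26), p23 (2.49), heat shock protein 83-1 (2.2) and aldolase (0.624), all of the 28-probe set, and for heat shock protein 70 in contig 2088 (−1.61). Control replicate 7 was the lowest control for hemocyanin in contig 807 (1.11 against 3.01 to 4.47) and contig 356 (0.678 against 2.56 to 3.96). The spike-in control feature a107 read 6.81 (log2) in cyfluthrin replicate 1 against 11.8 to 12.8 on the other exposed arrays.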

How the results depend on the processing

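The covariate of negative-control signal, the removal of arrays by detection or by spike-in feature a107 and the removal of the large rises were chosen after seeing the data. The counts moved by over 1.5 times under several settings, and the cause was not tested except where named. Probes higher numbered 196 with quantile normalization, 170 with normexp and quantile normalization, 64 with normexp and the 75th percentile, 259 with array weights, 302 with the negative-control covariate, 71 with at least 1.5-fold required and 173 at the looser threshold of 0.1. Probes lower numbered 79 with normexp and the 75th percentile, 434 with array weights, 124 without the 2 arrays of lowest detection (cyfluthrin replicates 2 and 4), 329 with the negative-control covariate and 347 at the looser threshold. The stricter and looser thresholds move counts by construction. With the replicate number as a block 120 probes were lower and 76 higher. The numbers do not pair the samples: correlations of same-numbered deviations ran from −0.13 to 0.44, 3 of 8 were over 0.1, and 1 of 8 controls correlated best with its own number. Leaving out 1 array gave 86 to 160 higher and 122 to 253 lower probes (122 without control replicate 4), 2 to 4 lists, −15.1 to −10.3 points in detection (exact p 0.00777 to 0.0421) and −0.0293 to 0.0493 in array distance. The deposited matrix holds nearly the same values as quantile normalization, and its counts (151 and 149) came out nearly alike (152 and 149) when quantile-normalized values were centred per probe, which removes the mean level that the variance trend uses. The number of shifted lists was 1 with normexp and the 75th percentile, 1 over probes well above background on all arrays, where fewer probes were tested, 0 with an estimated correlation and 5 by fry. The difference in detection kept its size with the replicate block (−12.9), with exact p = 0.0547. Array distance changed sign with normexp and quantile normalization (−0.000651) and over probes well above background on all arrays (−0.0262), never near the threshold. All 28 probes with large rises stayed called higher under each setting that tested them, while their median change of 3.49 was 2.38 with normexp and quantile normalization and 2.40 with normexp and the 75th percentile. Without these 28 probes 4 lists passed, the chaperone list downwards among them (adjusted p = 0.0422), but its risers were then left out for having risen, so this does not test the list.

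Of the named genes, 13 changed sign, each only with normexp and the 75th percentile, and the cause was not tested. Their log2 changes there were 0.072 for fructose-bisphosphatase, 0.13 for synaptic glycoprotein SC2, 0.21 for the muscarinic receptor, 0.25 for muscle LIM protein, 0.14 for chitinase 1, 0.067 for Niemann-Pick type C2 (contig 6516), 0.19 for a WD repeat protein (contig 1012), 0.015 for the lysozyme-like protein, 0.17 for the C-type lectin, 0.052 for a vacuolar ATP synthase subunit (contig 1270), −0.051 for a retinol dehydrogenase (contig 2197), 0.036 for aquaporin (contig 1389) and −0.058 for a Plasmodium-type protein (contig 958). In all other settings the named genes kept their direction, and of 2093 values 1949 stayed on the same side of the threshold, 37 came to pass it and the rest no longer did. Signal over background limits what can be said of dim probes.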

Other observations

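The tests in this part were chosen after the values were seen. Besides the hemocyanins, some contigs of other crustacean hemolymph proteins were lower in exposed animals. Clottable protein 2 (contig 1035) and hemolymph clottable protein (contig 1292), which form the clot at wounds, had log2 changes of −1.12 ± 0.29 and −1.06 ± 0.21 (SE). The former was well above background on 6 of 8 control arrays and 1 of 8 cyfluthrin arrays, and with normexp and the 75th percentile its log2 change was 0.17. A beta-glucan-binding protein, a sensor of fungal walls, fell in 3 contigs, with log2 changes of −0.97 ± 0.21 (contig 5594), −0.95 ± 0.24 (contig 3716) and −0.87 ± 0.17 (contig 191). With normexp and the 75th percentile contigs 1292, 5594 and 3716 did not pass and contig 191 did (−1.14). Further contigs of clottable protein 2 did not pass, with −0.815 (contig 1800) and −0.003 (contig 4837). Nor did those of hemolymph clottable protein, with 0.067 (contig 2010) and 0.255 (contig 2011). Over 18 tested hemolymph and clotting probes, 8 fell and none rose, while 14 had a negative and 4 a positive log2 change. That list was drawn up after the falls of its members were seen, so its camera p of 0.0316 with an estimated correlation does not bear on whether hemolymph proteins shifted as a group, which stays open.

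Proteins of ribosome assembly leaned upwards. Of 53 tested probes 43 had a positive log2 change, 7 rose and none fell, among them a pre-rRNA-processing protein TSR2 homolog (contig 3529, 0.73 ± 0.17 SE) and an mRNA turnover protein 4 homolog (contig 1081, 0.63 ± 0.11 SE). None of the 7 passed with normexp and the 75th percentile, where these had 0.52 and 0.35. This list too was drawn up after values were seen, and its camera p was 0.0584 with an estimated correlation of 0.261, so a shift of the whole group is left open.

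Nattectin (contig 1240), a C-type lectin named for a fish venom protein, was 3.66-fold higher after cyfluthrin (log2 change 1.87 ± 0.14 SE, adjusted p = 2.66e-07 by limma), outside the 28-probe set.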
